A study of Mus musculus with 26 samples.

How the data were processed

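The 26 columns analysed here are single-colour Affymetrix arrays of neurons sorted from mouse retina at postnatal day 6, 2 biological replicates from different litters for each of 13 subtypes. Per the labels, retinas were dissociated with papain, cells were sorted by reporter fluorescence with or without an antibody gate, and RNA was amplified in 2 rounds before biotin labelling. The values are intensities as deposited, on a linear scale with a floor at 1, and the software and scaling used to make them are not given in the sources used here. Between 2.87% and 4.02% of the values of an array equalled 1. The 12 ganglion cell columns and the 14 other columns lay on different scales, with mean medians of 69.3 and 43.8. No raw array files were used here.

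Values were taken as log2(intensity + 16), on which the floor lies at 4.09, and the 26 arrays were quantile normalized because their medians spread over 0.76 log2 units, above the limit of 0.2 for leaving the columns as they were. The 64 control probe sets were left out, as were 9160 probe sets without a gene symbol and 932 with several. Symbols came from the probe table of the array, updated by gene identifier for 34741 probe sets. Of the 34945 probe sets with a single symbol, the brightest stood for each of 18193 genes. A gene was tested if at least 2 of 26 arrays lay above the overall median (log2 6.14), which left 13951 genes.

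Genes were tested in R 4.3.3 with limma 3.58.1, with a group mean for each subtype, 13 residual degrees of freedom and empirical Bayes variances (4.59 prior degrees of freedom). Subtypes had equal weight within a side of a comparison. Tests were two-sided, adjusted by the Benjamini-Hochberg method within each of 15 comparisons. Errors therefore come from the replicates within a subtype, so class differences hold for these subtypes, and a setting with subtype means as units was also run. Amacrine transmitters came from labels for PaxCre and J and general knowledge for starburst and AII, and unlabelled MP was left out. Of 520 symbols in 38 gene lists, 444 were measured. The 37 lists with at least 3 measured members were tested with camera at an inter-gene correlation of 0.01, adjusted over 555 tests, and again with an estimated correlation. Members were in addition adjusted over the list alone.

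Genes are named by a rule: among genes that passed and were separated in every array, the 12 highest and 12 lowest for ganglion cells against amacrine cells, bipolar cells and starburst cells, 8 and 8 for GABAergic against glycinergic cells, and 8 and 4 for the others, with list members and the genes of lines and gates. Closeness of arrays was taken over the 2000 most variable genes by Pearson correlation and tested with 100000 permutations. The design, groups, comparisons, gene lists, naming rule, normalization limit and most alternatives were chosen before the data were examined. Bipolar cells against amacrine cells alone, subtype-restricted genes within a set of arrays and normalization within each set were added afterwards. Alternatives covered normalization, centring, filters, probe sets, pseudocounts, variance model, array weights, strain, line, and each array left out in turn. In simulated data with 200 changed genes per comparison, false calls numbered 0 to 10. Changes of 2 log2 units were found in 90% to 100%, of 1.5 in 72% to 100% and of 1 in 28% to 52%. Faults of a whole array were not simulated.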

Results

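RNA of 13 neuron subtypes of the mouse retina at postnatal day 6 was profiled on 26 arrays, 2 replicates per subtype. Cells were sorted by reporter fluorescence, mostly with an antibody gate. 6 subtypes were retinal ganglion cells, the output neurons of the retina, named BD, Cdh3, Isl2, J, W3 and W7, and all were sorted as Thy1-positive. 5 were amacrine cells, interneurons of the inner retina: starburst (Thy1-negative), MP (VC1.1-positive), AII, J and PaxCre. The remaining pair were bipolar cells, which carry photoreceptor signals to the inner retina: ON bipolar and MP bipolar (VC1.1-negative). Each array held 45037 probe sets besides 64 controls. Median intensity was 61.5 to 74.8 on the 12 ganglion cell arrays and 37.4 to 47.1 on the 14 amacrine and bipolar arrays, with maxima outside the controls of 11031 to 12077 and 6832 to 9281. The ganglion cell columns thus formed a scale set, which cannot be told apart from their class.

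Replicates of a subtype mostly resembled each other most. Over the 2000 most variable genes, the closest other array was the replicate of the same subtype for 24 of 26 arrays (permutation p = 1e-05, the smallest that 100000 resamples can give; the highest count in the resamples was 11). The exceptions lay within the ganglion cells: BD replicate 1 was closest to Isl2 replicate 1 (r = 0.962, against 0.900 with its own replicate) and Cdh3 replicate 1 was closest to BD replicate 1 (r = 0.921, against 0.905). Correlations across genes, which are not independent replicates, were 0.898 to 0.986 between replicates. Between classes they were 0.149 to 0.426 for ganglion cell with amacrine arrays, 0.410 to 0.697 for amacrine with bipolar arrays and 0.113 to 0.171 for ganglion cell with bipolar arrays.

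**Figure D1:**
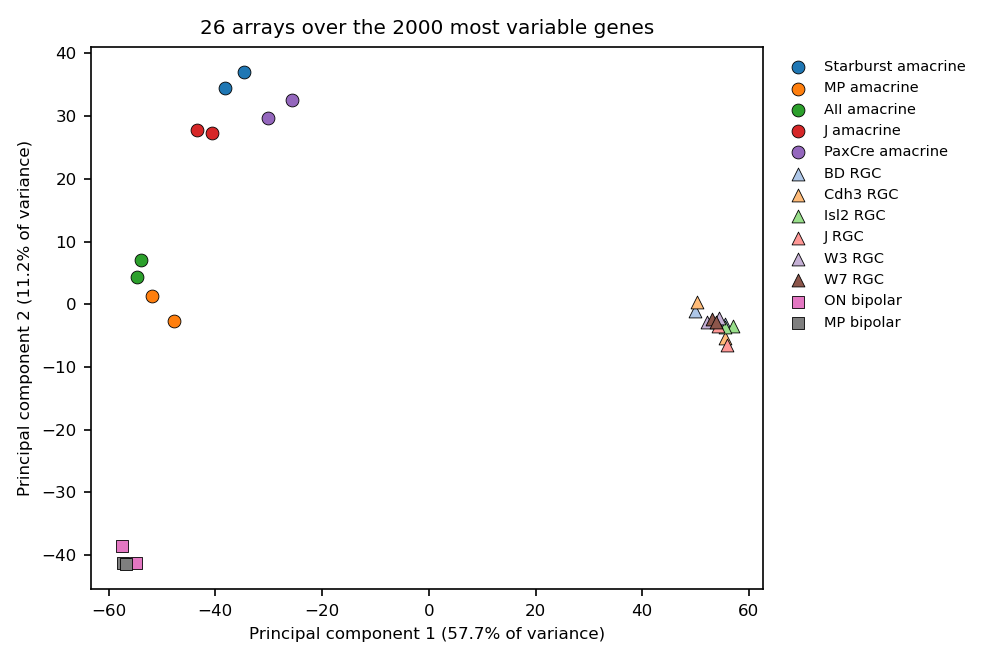
The first 2 principal components of the 26 arrays over the 2000 most variable genes, in log2 units, with 1 point per array, colour for the subtype and marker shape for the class. The first axis holds 57.7% of the variance and sets the 12 ganglion cell arrays apart from the other 14.

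Genes of gates and lines were read first. Thy1, a surface glycoprotein of ganglion cells, averaged 10.69 to 11.77 (log2, n = 2 per subtype) in the 6 ganglion cell subtypes and 5.22 ± 0.15 (SD, n = 2) in AII, 5.97 ± 0.53 in PaxCre and 5.03 ± 0.11 in ON bipolar cells. It reached 11.67 ± 0.32 in MP bipolar, 10.38 ± 0.62 in MP amacrine, 9.98 ± 0.49 in starburst and 8.80 ± 0.25 in J amacrine cells, the starburst cells having been sorted as Thy1-negative. Isl2, a LIM homeobox gene, was 8.15 ± 0.08 in Isl2 ganglion cells and at most 7.62 in any other subtype. The probe set of Cdh3 was too dim to be tested: its mean was 5.12 in Cdh3 ganglion cells, and without the filter on dim genes the difference from the other ganglion cells was 0.36 ± 0.17 (SE; limma adjusted p = 0.427). Pax6, a transcription factor of the amacrine and ganglion cell lineages, lay between 9.72 and 11.40 in all 11 amacrine and ganglion cell subtypes and at 5.86 and 5.95 in the ON and MP bipolar cells. Jam2 had its highest mean in J ganglion cells (11.07 ± 0.28).

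All comparisons below use limma over 13951 genes and all 26 arrays. A gene passed at an adjusted p under 0.05 and a difference of at least 1 log2 unit. Differences are given in log2(intensity + 16) with their SE, and those of low genes are understated on that scale. The ranked genes named in each comparison were in addition separated in every array of the sides compared. Gene lists were tested with camera.

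**Figure D2:**
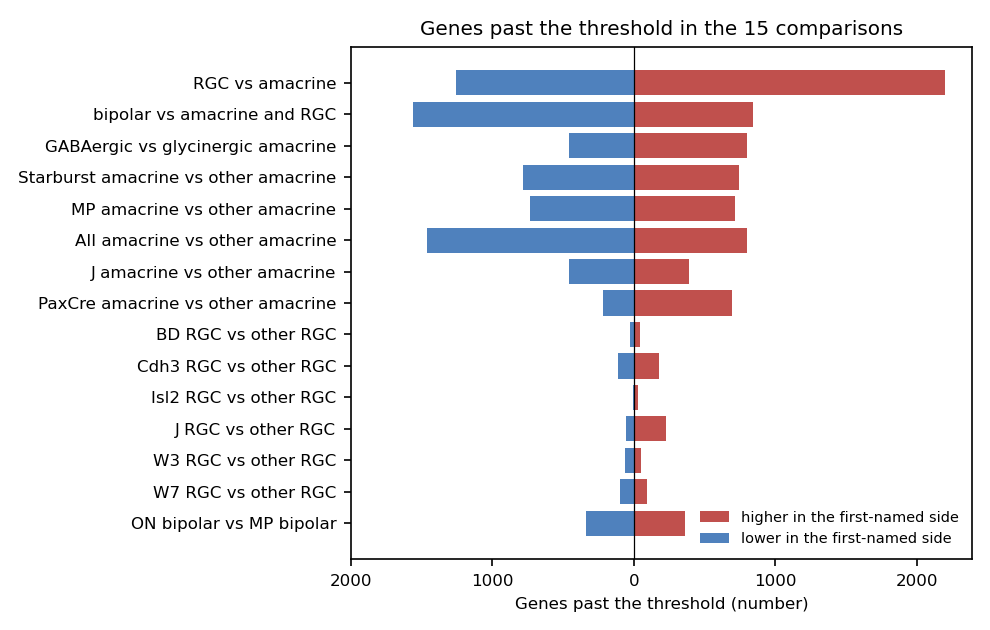
Number of genes past the threshold in each of the 15 comparisons, with bars to the right for higher and to the left for lower genes. Counts run from 31 for Isl2 ganglion cells to 3456 for ganglion cells against amacrine cells.

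Ganglion cells were first compared with amacrine cells (12 against 10 arrays). The gene with the largest rise in ganglion cells was Sncg, gamma-synuclein, at 6.84 ± 0.15 (115-fold, adjusted p = 4.33e-17). It was followed by the RNA-binding protein gene Rbpms at 6.25 ± 0.10 (76.2-fold), S100a10 at 6.23 ± 0.14, the POU-domain factor Pou4f1 at 6.03 ± 0.26 and Rnf19b at 6.02 ± 0.12. The other genes of the 12 highest were Rpl39, Rnasek, Slc17a6, the vesicular glutamate transporter (5.74 ± 0.19), Fn3krp, Serpinb6e, Ptpn6 and Opcml. The largest fall was that of Slc32a1, the vesicular transporter of GABA and glycine, at -6.65 ± 0.11 (adjusted p = 2.77e-18), with Cplx3 at -5.54 ± 0.09, U2af2 at -5.34 ± 0.12, Lbh at -4.79 ± 0.12 and the homeobox gene Prox1 at -4.59 ± 0.18. Fbxo32, Pnmt, Otx2, Vegfa, Ulk3, Krt24 and Dusp10 completed the 12 lowest, at -4.53 to -4.02. In all, 2201 genes were higher in ganglion cells and 1255 lower. Control probe sets moved with this comparison, 13 of 64 being separated between the 12 ganglion cell and 14 other arrays. As deposited, the 5-prime actin probe set averaged 469 against 151 (1.54 in log2, separated) and the 3-prime one 2170 against 2462 (not separated), and 5-prime Gapdh averaged 1130 against 669 (0.85 in log2, not separated).

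Of 18 measured ganglion cell markers, 15 rose, among them Nefl (4.04), Gap43 (3.96), Irx2 (3.40) and Thy1 (3.39), and 3 did not pass (15 passed when adjusted over the list alone, camera adjusted p = 3.73e-08). This was the 1 of 8 called lists that kept its call with an estimated correlation (adjusted p = 0.0328). Of 16 amacrine markers, 9 fell, led by Slc32a1, Tfap2b (-5.20) and Tfap2a (-4.42), and 3 rose: Calb2 (2.27), which encodes calretinin, Stx1a (1.41) and Gad2 (1.23), a GABA-synthesising enzyme. 4 did not pass, 12 passed when adjusted over the list alone, and the list as a whole was lower (camera adjusted p = 0.0188, adjusted p = 0.302 with an estimated correlation). Of 21 genes of the axon cytoskeleton and growth, 8 rose, with Map1b at 3.10 and Tubb3 at 2.81, and 13 did not pass (8 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.255 with an estimated correlation). Immunoglobulin superfamily adhesion genes split into 13 that rose, such as Sdk2 (4.09), Chl1 (4.05) and Cntn1 (2.16), 3 that fell, such as Jam3 (-1.68), and 10 that did not pass (16 adjusted over the list alone, camera adjusted p = 0.00712, adjusted p = 0.109 with an estimated correlation). Among 22 voltage-gated sodium and potassium channel genes, 12 rose, including Kcnd2, Kcna6 (3.36) and Kcnq3 (2.64), 2 fell, Kcng4 (-1.69) and Kcna4 (-1.52), and 8 did not pass (14 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.06 with an estimated correlation). Markers of microglia, immune cells, moved with these groups: all 9 measured rose, with C1qa at 4.18, Ctss at 4.17 and Aif1 at 2.78 (9 adjusted over the list alone, camera adjusted p = 0.00719, adjusted p = 0.511 with an estimated correlation). Their mean level was 7.62 to 10.27 in the ganglion cell subtypes and 5.48 to 7.03 in the others. Rod markers fell for 6 of 12, led by Sag (-2.88), and 6 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0365, adjusted p = 0.371 with an estimated correlation). That call ended with array weights and with a stricter filter (adjusted p = 0.0509 and 0.0675, in a range from 0.000887 to 0.371). In the J line alone Sag was at -1.14 (adjusted p = 0.189, the highest of a range from 2.22e-11). Vascular markers rose for 4 of 7, led by Rgs5 (3.98), and 3 did not pass (4 adjusted over the list alone), the list not being called (camera adjusted p = 0.343).

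With the columns as deposited, the median of all genes shifted by 0.53 towards ganglion cells, 4509 genes passed, and 85.8% of them were higher, against 63.7% after quantile normalization. The adhesion, channel and microglia lists kept their direction there and lost their calls (adjusted p = 0.091, 0.116 and 0.166). With the median over the probe sets of a gene, the adhesion and channel lists lost theirs as well (adjusted p = 0.0673 and 0.241). Over their alternatives the adjusted p ranged from 0.00169 to 0.109 for adhesion, from 0.0016 to 0.241 for channels and from 0.000595 to 0.511 for microglia. The next brightest probe set of Ptpn6, Lbh and Pnmt moved by 0.69, -0.02 and -0.37. With the median over probe sets Gad2, Cntn1 and Kcna6 were at 0.24, 0.44 and 0.25, Stx1a was at 0.55 in subtypes on C57BL/6 only, Kcng4 at -0.94 with a pseudocount of 64 and Kcna4 at -0.98 with the columns as deposited, all short of 1 log2 unit.

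Bipolar cells were next set against the average of both other classes (4 against 22 arrays). Cabp5 was 6.82 ± 0.30 higher (113-fold, adjusted p = 3.87e-12). Otor was 5.72 ± 0.25 higher and Gabrr1, a GABA receptor subunit gene, 5.42 ± 0.24. Tmem215, Otx2os1, the homeobox gene Otx2 (4.88 ± 0.27), Lrit1, Rgs9bp, Tafa3, Gem, the LIM homeobox gene Lhx4 (4.30 ± 0.22) and Lrp2bp followed, down to 4.28. The 12 lowest were Snhg11 (-5.98 ± 0.29), Ret (-5.48 ± 0.09), Lhfp (-5.48 ± 0.09), Id4, Calb2 (-4.80 ± 0.25), Pax6 (-4.76 ± 0.14, adjusted p = 4.09e-14), Gria3, Ubash3b, Cnr1, Glra2, Myt1l and Kif26a. The comparison gave 844 higher and 1560 lower genes.

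11 of 17 bipolar markers rose, among them Prdm8 (3.90), Gnb3 (3.70), Neurod4 (3.65) and Scgn (3.39), and 6 did not pass (11 adjusted over the list alone, camera adjusted p = 6.83e-08). Of 10 OFF bipolar markers, 6 rose, including Fezf2 (3.33) and Vsx1 (3.09), and 4 did not pass (6 adjusted over the list alone, camera adjusted p = 0.000444). Of 11 ON bipolar markers, 5 rose, with Pcp2 at 3.39 and Gng13 at 2.55, and 6 did not pass (5 adjusted over the list alone, camera adjusted p = 4.16e-05, adjusted p = 0.0602 with an estimated correlation). 15 of 18 ganglion cell markers fell, led by Stmn2 (-5.03), Nefm (-4.43) and Nefl (-4.12), with 3 not passing (15 adjusted over the list alone, camera adjusted p = 2.28e-08). 13 of 21 axon genes fell, such as Tubb3 (-2.31), and 8 did not pass (13 adjusted over the list alone, camera adjusted p = 3.24e-07). 11 of 22 sodium and potassium channel genes fell, led by Kcna1 (-3.96), Scn3b (-3.76) and Kcnq3 (-3.58), and 11 did not pass (11 adjusted over the list alone, camera adjusted p = 0.000145). Amacrine markers fell for 12 of 16 members and rose for Prox1 (1.64) and Neurod1, while 2 did not pass (14 adjusted over the list alone, camera adjusted p = 2.36e-05, adjusted p = 0.0713 with an estimated correlation). Rod photoreceptor markers moved with the bipolar genes: 7 of 12 rose, among them Gngt1 (3.88) and Sag (2.37), Gnb1 fell (-1.39), and 4 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00641, adjusted p = 0.267 with an estimated correlation). Microglia markers fell for 6 of 9, with 3 not passing (7 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.612 with an estimated correlation). That call ended with the columns as deposited (adjusted p = 0.229) and without MP bipolar replicate 2 (adjusted p = 0.0718), in a range from 0.00286 to 0.612. Muller glia markers fell for 2 of 11 and 9 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0409, adjusted p = 0.317 with an estimated correlation). The call ended in 9 of 38 alternatives (adjusted p from 0.0193 to 0.317), among them those without J amacrine replicate 1, MP bipolar replicate 1 or ON bipolar replicate 2 (adjusted p = 0.0543, 0.0737 and 0.0661).

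The columns as deposited gave 2778 genes, of which 17.6% were higher, against 35.1% after quantile normalization. Their median shift was -0.28. Bipolar against amacrine cells alone, a comparison inside 1 set of arrays that was added after seeing the data, gave 1446 genes, and in these Prox1 was at -0.65, Neurod1 at 0.59, Sag at 0.92 and Tubb3 at -0.91. The MP line alone gave 1168 genes, with Prox1 at -3.31, Neurod1 at -0.17, Sag at -0.11, Prdm8 at 0.17, Neurod4 at 0.07, Pcp2 at 0.62, Gng13 at 0.12, Gngt1 at 0.24, Gnb1 at -0.35, Tubb3 at -0.85 and Kcnq3 at -1.19, none of them called except Prox1, and Otx2 at 1.18 (adjusted p = 0.169, the highest of a range from 1.86e-12 over its alternatives). With a pseudocount of 64 Prox1 was at 0.94. With subtype means as units Prdm8, Kcna1, Prox1 and Neurod1 lost their calls (adjusted p = 0.064 to 0.276). In subtypes on C57BL/6 only, a setting that holds ON but not MP bipolar cells, Fezf2 was at 0.68. With the median over the probe sets of a gene, Pax6 was at -0.955 and Gnb1 at -0.91, and the next brightest probe sets of Lrp2bp, Ret and Cnr1 moved by 0.45, -0.28 and -0.05. Without ON bipolar replicate 1 or replicate 2, Lrp2bp was only 0.38 and 0.53 higher (adjusted p = 0.037 and 0.00531, in a range from 1.56e-12 to 0.037 over its alternatives).

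**Figure D3:**
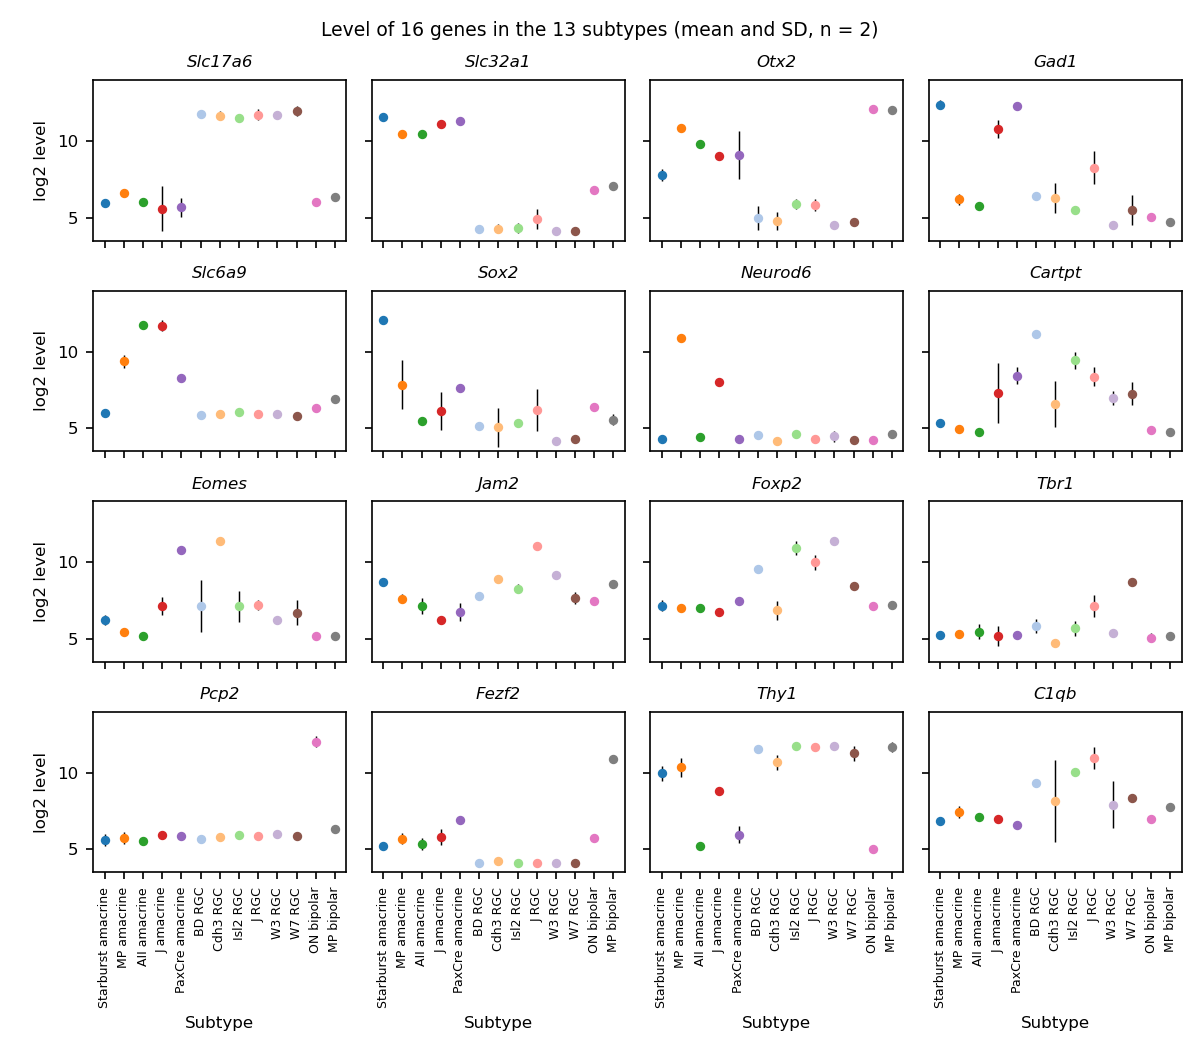
Level of 16 genes in the 13 subtypes as log2(intensity + 16), with points for the mean and bars for the SD of 2 arrays. Slc17a6 is high in the 6 ganglion cell subtypes, Slc32a1 in the 5 amacrine subtypes and Otx2 in both bipolar subtypes.

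GABAergic amacrine subtypes (starburst and PaxCre) were compared with glycinergic ones (AII and J, 4 against 4 arrays). Gad1, a GABA-synthesising enzyme, was 4.06 ± 0.34 higher on the GABAergic side (16.7-fold, adjusted p = 7.91e-08), and Slc6a9, the glycine transporter, was lower, at -4.57 ± 0.16 (adjusted p = 3e-12). The 8 highest genes were Stxbp6 (4.62 ± 0.37), Ankrd6, Igsf3, Gad1, Sox2 (4.05 ± 0.49), Rbms1, Tpbg and Pdgfa. The 8 lowest were Lamp5 (-6.20 ± 0.67), the Wnt-pathway receptor gene Lgr5 (-5.17 ± 0.29), Ppp1r17 (-4.91 ± 0.24), Krt24, Slc6a9, St18, Phldb2 and Shisa6. In total, 801 genes were higher and 455 lower.

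Of 7 glycinergic markers, 4 fell, Slc6a9, Tcf4 (-3.10), Ebf1 (-3.08) and Ebf3 (-2.70), and 3 did not pass (4 adjusted over the list alone, camera adjusted p = 0.000543, adjusted p = 0.0533 with an estimated correlation). 2 of 6 GABAergic markers rose and 4 did not pass (2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.14). A median over probe sets and a pseudocount of 64 gave adjusted p = 0.00526 and 0.0455, in a range from 0.00526 to 0.503 over its alternatives. As starburst and AII cells lie on opposite sides, their marker lists cannot test transmitter. 8 of 10 starburst markers rose, such as Tenm3 (3.44) and Isl1 (2.59), and 2 did not pass (8 adjusted over the list alone, camera adjusted p = 1.24e-08). AII markers fell for 4 of 9, including Dab1 (-3.79) and Prox1 (-3.49), rose for Calb2 and did not pass for 4 (5 adjusted over the list alone, camera adjusted p = 4.09e-06). Delta protocadherins rose for 6 of 9 members, with Pcdh7 at 3.56 and Pcdh9 at 3.39, and fell for Pcdh11x (-2.14) and Pcdh19 (-1.79), with 1 not passing (8 adjusted over the list alone, camera adjusted p = 0.00607, adjusted p = 0.0824 with an estimated correlation). The protocadherin call ended with the median over probe sets (adjusted p = 0.0657, in a range from 0.00164 to 0.0824), where Pcdh7 was at 0.96. Neuropeptide genes rose for 5 of 14 and 9 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00702, adjusted p = 0.255 with an estimated correlation). Npy (3.32) and Pnoc (2.41) were at least 3.96 and 3.43 higher in starburst cells than in any other subtype. Crh (3.21) ranked first in PaxCre cells, so each followed 1 subtype. Immediate early and stress genes rose for 3 of 12, with Jun at 1.67, and 9 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.425 with an estimated correlation). The call ended in 14 of 38 alternatives (adjusted p from 0.0187 to 0.425), among them those without replicate 2 of AII, J amacrine, MP amacrine or starburst cells, PaxCre replicate 1 or any J or W7 ganglion cell array (adjusted p = 0.0504 to 0.0986). Their mean level was 7.42 in J amacrine, 7.95 in AII, 8.32 in starburst and 8.38 in PaxCre cells. Progenitor genes rose for 4 of 12 and 8 did not pass (4 adjusted over the list alone), the list not being called (camera adjusted p = 0.274). The next probe sets of Ankrd6, Pdgfa and St18 moved by 0.65, 0.47 and -0.26. Shifting each array to the same median moved the median of all genes by 0.12 in this comparison and by -0.12 for AII cells, and the columns as deposited moved it by 0.11 for Cdh3 ganglion cells.

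Each amacrine subtype was then compared with the mean of the others (2 against 8 arrays). Starburst cells, which are cholinergic, differed in 742 higher and 782 lower genes. Sox2ot (6.37 ± 0.37, 82.7-fold, adjusted p = 4.01e-10) and Sox2 (5.32 ± 0.54) were higher together, with Tgfb3 at 6.23 ± 0.22, Moxd1 at 6.12 ± 0.31, Lmo7 at 5.78 ± 0.20 and Megf10 at 5.71 ± 0.43. Islr2, Csrp3, Pkp1, Pappa2, the calcium-binding protein gene Calb1 and Etl4 completed the 12 highest. The lowest were Sphkap (-5.82 ± 0.16), Prdm8 (-5.74 ± 0.33), the sodium channel gene Scn1a (-5.28 ± 0.18), Pnmal2, St18, Pcdh11x (-5.03 ± 0.33), Nckap5, Zfp804a, Tmem215, Necab1, Gfra2 and Dscaml1.

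9 of 10 starburst markers rose, among them Isl1 (4.43), Slc18a3, the vesicular acetylcholine transporter (3.49), and Chat, the enzyme of acetylcholine synthesis (1.89), while Slc5a7 did not pass (0.26; 9 adjusted over the list alone, camera adjusted p = 7.4e-12). Of the 9 AII markers, 6 fell, Calb2 rose (2.62) and 2 did not pass (7 adjusted over the list alone, camera adjusted p = 1.48e-06). Markers of amacrine cells with neither GABA nor glycine fell for 4 of 5, with Neurod2 at -4.01, and 1 did not pass (4 adjusted over the list alone, camera adjusted p = 1.92e-06). Of 22 sodium and potassium channel genes, 10 fell, including Scn3a (-4.17) and Kcna1 (-4.06), 2 rose, Kcnc2 (1.75) and Scn2b (1.52), and 10 did not pass (12 adjusted over the list alone, camera adjusted p = 0.000262). The neurexin and neuroligin list had 5 that fell of 13, led by Cbln4 (-3.18) and Nlgn1 (-2.05), with 8 not passing (5 adjusted over the list alone, camera adjusted p = 0.00164). The GABAergic marker list was lower although Gad1 rose (3.62): Tfap2c (-4.53), Meis2 (-4.46), Maf (-3.69) and Lhx9 (-2.07), factors of other GABAergic amacrine cells, fell, and 1 did not pass (5 adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.267 with an estimated correlation). Classical cadherins split, with Cdh1 (4.57) and Cdh6 (2.35) higher, 6 lower, such as Cdh22 (-2.93) and Cdh13 (-2.90), and 5 not passing (8 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.0997 with an estimated correlation). Rod markers fell for 6 of 12, such as Pde6b (-1.86), with 6 not passing (6 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.317 with an estimated correlation). It lost its call without starburst replicate 2 (adjusted p = 0.0522, in a range from 0.000968 to 0.317). Bipolar markers fell for 4 of 17, rose for 1 and did not pass for 12 (6 adjusted over the list alone, camera adjusted p = 0.0188, adjusted p = 0.299 with an estimated correlation). Its call ended without J amacrine replicate 2 (adjusted p = 0.0528, in a range from 0.00674 to 0.299). The next probe set of St18 moved by -0.20, and with the median over probe sets Cdh13 was at 0.01 and Scn2b at 0.15. Without starburst replicate 2 Nlgn1 and Pde6b lost their calls (adjusted p = 0.0729 to 0.233).

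MP amacrine cells differed in 716 higher and 734 lower genes. The basic helix-loop-helix factor Neurod6 was 5.63 ± 0.14 higher (49.7-fold, adjusted p = 1.21e-14), with Rgs13 at 5.22 ± 0.44, Ebf3 at 5.17 ± 0.32, Nfix at 5.06 ± 0.30 and the calcium channel subunit gene Cacna2d3 at 4.54 ± 0.27. Selenop (4.36 ± 1.09), Gngt1, a rod transducin subunit gene (3.75 ± 0.78), and Frem1 followed. The metabotropic glutamate receptor gene Grm3 was lowest (-4.99 ± 0.32), before Cacng5, Rbfox1 and Kcna5 (-4.22 ± 0.40). Markers of amacrine cells with neither GABA nor glycine rose for 4 of 5, including Ppp1r17 (3.55), and Gbx2 did not pass (-0.82; 4 adjusted over the list alone, camera adjusted p = 0.000206, adjusted p = 0.0533 with an estimated correlation). Glycinergic markers rose for 3 of 7, Ebf3, Ebf1 (4.74) and Tcf4 (2.14), all transcription factors, while Slc6a9 was at -0.07 and 4 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.142 with an estimated correlation). Of 13 neurexin and neuroligin genes, 4 fell, among them Cbln4 (-3.84) and Cbln2 (-2.69), and 9 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00164). 6 of 9 delta protocadherins fell, such as Pcdh18 (-3.50), Pcdh8 rose (1.66) and 2 did not pass (7 adjusted over the list alone, camera adjusted p = 0.00655, adjusted p = 0.0829 with an estimated correlation). That call ended with the median over probe sets (adjusted p = 0.127, the highest of a range from 0.00221). Markers of rods moved with these groups: 8 of 12 rose, with Samd7 at 2.89 and Nrl at 2.29, and 4 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.218 with an estimated correlation). Bipolar markers rose for 7 of 17, with Prdm8 at 3.32 and Otx2 at 1.97, fell for 2 and did not pass for 8 (9 adjusted over the list alone, camera adjusted p = 0.0194, adjusted p = 0.299 with an estimated correlation). Without MP amacrine replicate 1 that call ended (adjusted p = 0.112, in a range from 0.00261 to 0.299). Immediate early and stress genes rose for 3 of 12, with Jun at 1.49, and 9 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00702, adjusted p = 0.299 with an estimated correlation). Leaving out MP amacrine replicate 2 ended the calls of Selenop (adjusted p = 0.117, the highest of a range from 0.000847 over its alternatives) and Jun (adjusted p = 0.168, the highest of a range from 0.00223). Shifting each array to the same median left 38.6% of called genes higher, against 49.4% after quantile normalization.

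AII cells differed in 800 higher and 1459 lower genes. Hao2 was 6.08 ± 0.21 higher (67.8-fold, adjusted p = 2.19e-12), followed by S100a9 (5.15 ± 0.25), Cdh1 (5.13 ± 0.29), Dync1i1 (4.93 ± 0.26), the potassium channel gene Kcnh1, Actc1, Anxa1 and Slc24a2 (4.48 ± 0.25). S100a9 encodes a calcium-binding protein of neutrophils, and other genes of neutrophils and myeloid cells, picked after their values were seen, rose with it: Olfm4 (4.44), S100a8 (4.23), Stfa2l1 (4.02) and Clec4d (1.63). The median of 4 further neutrophil genes was -0.13, and none of them passed. The lowest were Crabp1 (-6.31 ± 0.39), Spock1 (-6.13 ± 0.21), Sulf2 and Tmsb10. Of 9 AII markers, 7 rose, such as Nfia (4.43), Dab1 (3.65), Prox1 (3.42) and Gjd2, connexin 36 (2.75), while Nfib (-1.57) and Nfix (-1.45) fell (9 adjusted over the list alone, camera adjusted p = 1.53e-05, adjusted p = 0.0533 with an estimated correlation). Delta protocadherins fell for 5 of 9, led by Pcdh10 (-4.19) and Pcdh8 (-4.17), rose for Pcdh19 (1.19) and did not pass for 3 (6 adjusted over the list alone, camera adjusted p = 0.00101, adjusted p = 0.0514 with an estimated correlation). Of 6 GABAergic markers, 5 fell, with Gad1 at -4.67, and 1 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00314, adjusted p = 0.206 with an estimated correlation). 6 of 14 neuropeptide genes fell, such as Npy (-3.92) and Tac1 (-2.89), and 8 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00532, adjusted p = 0.232 with an estimated correlation). Ganglion cell markers fell for 9 of 18, among them Thy1 (-3.56), and 9 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000537, adjusted p = 0.141 with an estimated correlation). Markers of Muller glia fell for 6 of 11, with Glul at -2.78, and 5 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.228 with an estimated correlation). The next probe sets of Slc24a2 and Sulf2 moved by -0.02 and -0.61. Nfib lost its call without either AII array (adjusted p = 0.115 and 0.117, in a range from 0.000689 to 0.117), and with the median over probe sets Nfib and Nfix were at -0.86 and -0.97.

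J amacrine cells, a glycinergic subset by the labels, differed in 391 higher and 455 lower genes. Loxl1 was 5.10 ± 0.52 higher (34.3-fold, adjusted p = 3.26e-06), with the cadherin gene Cdh22 at 4.51 ± 0.19, Nr4a2 at 4.50 ± 0.37, Snai2 at 4.34 ± 0.52, Shisa9, Fgf18, the GABA receptor subunit gene Gabrb1 (3.73 ± 0.21) and Tmem215. The lowest were Isl1 (-4.43 ± 0.30), Calb2 (-3.32 ± 0.37), Sema3d and Myb. Glycinergic markers rose for 4 of 7, including Slc6a9 (2.84) and Ebf1 (4.85), and 3 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.071 with an estimated correlation). GABAergic markers rose too, for 4 of 6, Meis2 (3.11), Tfap2c (2.95), Gad1 (1.66) and Lhx9 (1.53), while Gad2 was at -0.63 and 2 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.18 with an estimated correlation). That call ended without J amacrine replicate 1 (adjusted p = 0.053, in a range from 0.000282 to 0.18). Of the 13 neurexin and neuroligin genes, 5 rose, among them Cbln4 (3.16) and Cbln1 (2.28), C1ql3 fell (-1.52) and 7 did not pass (7 adjusted over the list alone, camera adjusted p = 1.13e-05). Delta protocadherins rose for 3 of 9, Pcdh18 (2.79), Pcdh11x (2.48) and Pcdh10 (1.70), and 6 did not pass (3 adjusted over the list alone, camera adjusted p = 5.56e-05). Starburst markers fell for 4 of 10, rose for Gad1 and did not pass for 5 (5 adjusted over the list alone, camera adjusted p = 0.000262). Immediate early and stress genes moved with these groups: 5 of 12 fell, with Jun at -1.83 and Fos at -1.66, and 7 did not pass (6 adjusted over the list alone, camera adjusted p = 0.000185, adjusted p = 0.15 with an estimated correlation). J amacrine arrays also had the largest 3-prime over 5-prime signal difference of Gapdh, 4.04 and 4.15 in log2, against 1.45 to 3.48 on the other 24 arrays. Rod markers fell for 2 of 12 and 10 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.36 with an estimated correlation). Ganglion cell markers rose for 2 of 18, fell for 1 and did not pass for 15 (4 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.294 with an estimated correlation). Both calls ended without J amacrine replicate 2 (adjusted p = 0.25 and 0.176), in ranges from 0.00239 to 0.36 and from 0.00188 to 0.294, and the rod call without replicate 1 of PaxCre or starburst cells and with array weights (adjusted p = 0.0508, 0.0513 and 0.0572). Jun, Fos and C1ql3 lost their calls without J amacrine replicate 2 (adjusted p = 0.0526 to 0.216), Gad1 without replicate 1 (adjusted p = 0.115, the highest of a range from 0.00267), and Gad1 and Fos with array weights (adjusted p = 0.0578 and 0.142). With the median over probe sets Tfap2c, Gad1 and Pcdh10 were at 0.75, 0.89 and 0.83, and with a pseudocount of 64 Lhx9 and C1ql3 were at 0.71 and -0.84.

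PaxCre cells, a GABAergic subset by the labels, differed in 694 higher and 218 lower genes. Crh, a neuropeptide gene, was 5.87 ± 0.41 higher (58.5-fold, adjusted p = 1.5e-08), with the matrix gene Tnc at 5.33 ± 0.31, the LIM homeobox gene Lhx9 at 5.30 ± 0.33, the peptide gene Tac1 at 5.20 ± 0.29, the chemokine gene Cxcl12 at 5.02 ± 0.51, Aldh1a1, the T-box gene Eomes (4.83 ± 0.44) and Efemp1. The lowest were Spsb4 (-3.67 ± 0.23), Ret (-3.65 ± 0.14), Crtac1 and Tbx2. GABAergic markers rose for 5 of 6, including Maf (4.63), Tfap2c (4.14) and Gad1 (3.51), and Gad2 did not pass (0.51; 5 adjusted over the list alone, camera adjusted p = 1.24e-08). All 9 delta protocadherins rose, from Pcdh18 at 1.03 to Pcdh7 at 3.20 (9 adjusted over the list alone, camera adjusted p = 1.7e-11). Of 17 teneurin, netrin and slit pathway genes, 9 rose, with Robo1 at 4.11 and Tenm4 at 2.79, and 8 did not pass (9 adjusted over the list alone, camera adjusted p = 1.07e-05). Of 26 immunoglobulin superfamily genes, 11 rose, such as Alcam (2.95), Cntn6 fell (-2.19) and 14 did not pass (12 adjusted over the list alone, camera adjusted p = 0.000191). 9 of 22 sodium and potassium channel genes rose, with Kcna1 at 3.42, and 13 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000241). Of 13 neurexin and neuroligin genes, 6 rose, led by C1ql2 (3.24), and 7 did not pass (7 adjusted over the list alone, camera adjusted p = 3.5e-07). Glycinergic markers fell for 4 of 7, rose for Lmo4 (1.30) and did not pass for 2 (5 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.0815 with an estimated correlation). Progenitor and cell cycle genes moved with these groups: Mki67 (2.74), Top2a (2.36), Sfrp2 (1.94) and Ccnd1 (1.33) rose and 8 of 12 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00374, adjusted p = 0.276 with an estimated correlation). Muller glia markers rose for 3 of 11 and 8 did not pass (4 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.317 with an estimated correlation). The call ended in 9 of 38 alternatives (adjusted p from 0.00278 to 0.317), among them those without replicate 2 of AII, J amacrine or starburst cells or MP amacrine replicate 1 (adjusted p = 0.0552 to 0.0863). The count fell to 596 without PaxCre replicate 2, and the next probe set of Ret moved by -0.34. Without that array Pcdh18, Mki67 and Ccnd1 lost their calls (adjusted p = 0.0617 to 0.289), and Ccnd1 also without PaxCre replicate 1 (adjusted p = 0.16, the highest of a range from 0.00139). Pcdh18 kept its call in 30 of 38 alternatives. Pcdh18 and Ccnd1 lost theirs with only the compared arrays (adjusted p = 0.0547 and 0.0624), and with the median over probe sets Pcdh18 was at -0.67, Top2a at -0.09 and Pcdh7 at 0.89.

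Each ganglion cell subtype was compared with the mean of the other 5 (2 against 10 arrays). BD cells, ganglion cells with a bistratified dendrite, had 44 higher and 25 lower genes. The neuropeptide gene Cartpt was 3.46 ± 0.54 higher (11-fold, adjusted p = 0.00315), with Niban1 at 2.71 ± 0.19, Olfm3 at 2.71 ± 0.29, the transcription factor gene Tfap2d at 2.66 ± 0.26, Col25a1 at 2.60 ± 0.34, Rab27b, Tafa1 and Gabra4. Klf9 (-2.17 ± 0.37), Ptprg, Gda and Caln1 were lowest. Of 5 markers of ON-OFF direction-selective ganglion cells, 4 rose, Cartpt, Col25a1, Cdh6 (2.12) and Satb1 (1.64), and Mmp17 did not pass (0.56; 4 adjusted over the list alone, camera adjusted p = 3.8e-13). None of the 23 leucine rich repeat adhesion genes passed in limma, with 8 lower at an unadjusted p under 0.05 and 2 adjusted over the list alone, while the list as a whole was lower (camera adjusted p = 0.000767, adjusted p = 0.0533 with an estimated correlation). Without BD replicate 2, 10 genes passed and 9 of the 12 named genes lost their call (adjusted p = 0.0909 to 1); Niban1, Olfm3 and Tfap2d kept it. All 4 direction-selective cell markers lost theirs there, Cartpt and Col25a1 among those 9, and Cdh6 and Satb1 (adjusted p = 0.137 and 0.0972), in ranges from 0.000223 to 0.137 and from 0.000135 to 0.0972. Cdh6 also did with array weights (adjusted p = 0.0713). Without BD replicate 1, 822 genes passed. The next probe sets of Col25a1, Gabra4, Klf9, Ptprg and Caln1 moved by -0.15, 0.74, -0.58, -0.83 and -0.47.

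Cdh3 ganglion cells had 176 higher and 115 lower genes. Eomes, a T-box gene, was 4.48 ± 0.43 higher (22.3-fold, adjusted p = 3.95e-06), followed by Cdh1, E-cadherin (4.26 ± 0.29), Shisa6 (4.25 ± 0.28), the receptor gene Gpr6 (4.14 ± 0.21), Vat1l, Etl4, Ndnf and the T-box gene Tbx20 (3.52 ± 0.17). The lowest were the transcription factor genes Meis2 (-4.14 ± 0.35), Foxp2 (-3.21 ± 0.22) and Bcl11b (-3.05 ± 0.49), and Crh (-4.07 ± 0.40). Of 6 markers of intrinsically photosensitive ganglion cells, 3 rose, Eomes, Tbx20 and Opn4, which encodes melanopsin (3.29), and 3 did not pass (3 adjusted over the list alone, camera adjusted p = 2.04e-06). Amacrine markers fell for 4 of 16, Meis2, Barhl2 (-2.38), Neurod1 (-1.75) and Tfap2c (-1.68), and 12 did not pass (4 adjusted over the list alone, camera adjusted p = 6.47e-05, adjusted p = 0.0829 with an estimated correlation). 4 of 23 leucine rich repeat adhesion genes rose, such as Lrrc4c (1.54), and 19 did not pass (5 adjusted over the list alone, camera adjusted p = 0.000313). No microglia marker passed in limma, 0 of 9 had an unadjusted p under 0.05, 0 passed when adjusted over the list alone, and the list was lower (camera adjusted p = 0.00532, adjusted p = 0.491 with an estimated correlation). The microglia list turned to the higher side without Cdh3 replicate 2 (adjusted p = 0.0514, in a range from 1.29e-12 to 0.491). Horizontal cell markers rose for 3 of 5 and 2 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.18 with an estimated correlation). Its call ended without Cdh3 replicate 1 or J ganglion cell replicate 2 and with a stricter filter (adjusted p = 0.127, 0.0505 and 0.258, in a range from 0.00628). Without Cdh3 replicate 2, 175 genes passed, and Bcl11b, Neurod1, Tfap2c and Lrrc4c lost their calls (adjusted p = 0.0884 to 0.331). Tfap2c kept its call in 30 of 38 alternatives (adjusted p = 0.000873 to 0.289). The next probe sets of Etl4 and Ndnf moved by 0.02 and 0.11, and with the median over probe sets Etl4 lost its call at 0.28 (adjusted p = 0.715, the highest of a range from 1.2e-10).

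Isl2 ganglion cells had 27 higher and 4 lower genes. Apart from Isl2 itself, 1.22 ± 0.19 higher (adjusted p = 0.00429), the highest were Pf4, a chemokine gene of platelets and macrophages (4.66 ± 0.42, 25.2-fold, adjusted p = 1.43e-05), F13a1 (3.04 ± 0.18), the chemokine gene Cxcl2 (2.51 ± 0.26), Mrc1, the macrophage mannose receptor (2.13 ± 0.22), Rarres1, Runx1 (1.98 ± 0.20), Rhox5 and Npas4. No lower gene met the naming rule. Microglia markers moved with them as a list (camera adjusted p = 5.56e-05, adjusted p = 0.322 with an estimated correlation), with none of 9 passing in limma, 3 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone. Immediate early and stress genes were higher as a list (camera adjusted p = 3.06e-06, adjusted p = 0.0772 with an estimated correlation), with none of 12 passing in limma, 7 higher at an unadjusted p under 0.05 and 2 adjusted over the list alone. The count was 9 without Isl2 replicate 1, 8 without Isl2 replicate 2, 61 without BD replicate 1 and 57 without Cdh3 replicate 1. Rarres1, Npas4 and Isl2 itself lost their calls without either Isl2 array (adjusted p = 0.0929 to 1). With only the compared arrays Isl2 lost its call (adjusted p = 0.0534, in a range from 1.74e-05 to 0.264), and with a pseudocount of 64 it was at 0.93. Rhox5 lost its call with only the compared arrays (adjusted p = 0.0824, the highest of a range from 2.41e-06 over its alternatives).

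J ganglion cells had 227 higher and 58 lower genes. Jam2 was 2.70 ± 0.23 higher (adjusted p = 1.09e-05). The 8 highest held genes of basement membrane and vessel walls, Nid1 (3.74 ± 0.85, 13.4-fold, adjusted p = 0.0213), Bgn (3.34 ± 0.71), Abcc9 (3.32 ± 0.80) and Igfbp7 (3.12 ± 0.61), beside the transcription factor genes Tfap2c (3.72 ± 0.42) and Prdm8 (3.14 ± 0.32), Anxa1 (3.58 ± 0.49) and the lipoprotein gene Apoe (3.12 ± 0.82). The lowest were Igfbp5 (-2.29 ± 0.39), Cacna2d3, Zfp248 and Ppp1r1c (-1.73 ± 0.21). Markers of other cells moved with them. Of 7 vascular markers, Col4a1 rose (2.81) and 6 did not pass, with Pdgfrb at 3.55 and Rgs5 at 2.61 (3 adjusted over the list alone, camera adjusted p = 0.00218, adjusted p = 0.141 with an estimated correlation). Of 9 microglia markers, Aif1 (1.73) and Fcer1g rose and 7 did not pass (8 adjusted over the list alone, camera adjusted p = 2.76e-07, adjusted p = 0.218 with an estimated correlation). Of 11 Muller glia markers, Apoe, Id3 (2.68) and Crym (1.76) rose and 8 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00222, adjusted p = 0.15 with an estimated correlation). Amacrine markers rose for 4 of 16, Tfap2c, Gad1 (2.61), Tfap2b (2.48) and Tfap2a, and 12 did not pass (5 adjusted over the list alone, camera adjusted p = 8.84e-06, adjusted p = 0.0602 with an estimated correlation). Progenitor genes rose for 3 of 12, with Mki67 at 2.01, and 9 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.218 with an estimated correlation). Immediate early and stress genes were higher as a list, with none of 12 passing, 3 higher at an unadjusted p under 0.05 and 3 adjusted over the list alone (camera adjusted p = 0.0169, adjusted p = 0.342 with an estimated correlation). Without J replicate 1 that call ended (adjusted p = 0.213, in a range from 0.00338 to 0.342). Without J replicate 2, 40 genes passed and 9 of the 12 ranked genes lost their call (adjusted p = 0.0624 to 0.583), with Tfap2c, Prdm8 and Ppp1r1c keeping it; without J replicate 1, Nid1, Bgn, Abcc9 and Apoe lost theirs (adjusted p = 0.067 to 0.116). Col4a1, Aif1, Id3 and Mki67 lost theirs without either J array (adjusted p = 0.0671 to 0.422), Fcer1g without J replicate 2 (adjusted p = 0.22, the highest of a range from 0.000676) and Tfap2a without J replicate 1 (adjusted p = 0.739, the highest of a range from 0.000487). Of 38 alternatives, Apoe kept its call in 15 (adjusted p = 0.00357 to 0.583), Mki67 in 17, Tfap2a in 26 and Aif1 in 29. With the median over probe sets Jam2 was at 0.66 (adjusted p = 0.111, the highest of a range from 9.93e-07), and Pdgfrb and Rgs5 passed (adjusted p = 0.0152 and 0.00891, in ranges from 0.00286 to 0.404 and from 0.00891 to 0.655). The next probe sets of Tfap2c, Igfbp7, Igfbp5 and Zfp248 moved by 0.40, 0.32, 0.04 and 0.57.

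W3 ganglion cells had 48 higher and 64 lower genes. The carbonic anhydrase gene Car3 was 3.21 ± 0.45 higher (9.24-fold, adjusted p = 0.000725), with the receptor gene Prokr1 at 2.58 ± 0.29, Trarg1 at 2.53 ± 0.34, the forkhead gene Foxp2 at 2.23 ± 0.22, Cdkl4 at 2.12 ± 0.23, the kainate receptor subunit gene Grik3 at 1.91 ± 0.28, Car2 and Pcdh7. The growth factor gene Igf1 was lowest (-3.20 ± 0.30, adjusted p = 3.31e-05), then Cdh6 (-2.78 ± 0.28), Mndal and Ndnf. Markers of ON-OFF direction-selective cells were lower as a list: Cdh6 fell and 4 of 5 did not pass (2 adjusted over the list alone, camera adjusted p = 4.12e-05). Of 13 classical cadherins, Cdh6 and Cdh1 (-1.97) fell and 11 did not pass (3 adjusted over the list alone, camera adjusted p = 0.000588). None of 5 alpha ganglion cell markers passed in limma, with 3 lower at an unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p = 0.00125). Microglia markers were lower as a list (camera adjusted p = 3.15e-05, adjusted p = 0.307 with an estimated correlation), with none of 9 passing in limma, 6 lower at an unadjusted p under 0.05 and 1 adjusted over the list alone. Vascular markers were lower with none of 7 passing, 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.266 with an estimated correlation). Both calls ended without W3 replicate 2 (adjusted p = 0.155 and 0.336), and the vascular call without Cdh3 replicate 1 (adjusted p = 0.0535), in ranges from 1.94e-11 to 0.307 and from 0.00259 to 0.336. Genes of immediate early and stress responses fell for 1 of 12 and 11 did not pass (1 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.218 with an estimated correlation). Progenitor genes fell for 1 of 12 and 11 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.352 with an estimated correlation). Its call ended without BD or W3 replicate 1 (adjusted p = 0.0652 and 0.226, in a range from 0.000756 to 0.352). Horizontal cell markers fell for 1 of 5 and 4 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0164, adjusted p = 0.174 with an estimated correlation). Amacrine markers fell for 2 of 16 and 14 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0366, adjusted p = 0.343 with an estimated correlation). Both calls ended without W3 replicate 2 (adjusted p = 0.287 and 0.219) and with the median over probe sets (adjusted p = 0.0638 and 0.0714), in ranges from 0.000835 to 0.287 and from 0.00089 to 0.343, and the amacrine call without either BD array or J replicate 1 (adjusted p = 0.0528 to 0.0633) and with a pseudocount of 64 (adjusted p = 0.114). The count was 41 without W3 replicate 2, 73 without W3 replicate 1 and 188 without Cdh3 replicate 2. Cdh1 lost its call with only the compared arrays (adjusted p = 0.0573, the highest of a range from 5.01e-05). Car2 lost its call without either W3 array or Isl2 replicate 1 (adjusted p = 0.0536 to 0.33) and Mndal without W3 replicate 2 (adjusted p = 0.0666, the highest of a range from 4.78e-05 over its alternatives). The next probe sets of Car3, Pcdh7, Cdh6 and Ndnf moved by 0.98, 0.31, -0.22 and -0.10.

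W7 ganglion cells had 95 higher and 96 lower genes. Crh was 4.12 ± 0.40 higher (17.4-fold, adjusted p = 1.11e-05), with Tbr1, a T-box gene, at 2.99 ± 0.27, Coch at 2.78 ± 0.30, Ctxn3, Cemip (2.74 ± 0.17), the nuclear receptor gene Esrrg (2.72 ± 0.35), Nxph1 and the glycine receptor subunit gene Glra1 (2.51 ± 0.37). Adgrg2 (-2.24 ± 0.24), Tac1 (-2.18 ± 0.29), Marchf1 and Fxyd6 were lowest. Alpha ganglion cell markers rose for 3 of 5, Tbr1, the neurofilament gene Nefh (1.66) and Cntnap4 (1.31), and 2 did not pass (3 adjusted over the list alone, camera adjusted p = 5.5e-06). Of 22 sodium and potassium channel genes, Kcna1 rose (1.73) and 21 did not pass (1 adjusted over the list alone), and the list as a whole was higher (camera adjusted p = 0.000614). Horizontal cell markers were lower: Tfap2b fell (-1.81) and 4 of 5 did not pass (2 adjusted over the list alone, camera adjusted p = 0.00519, adjusted p = 0.107 with an estimated correlation). That call ended with the median over probe sets (adjusted p = 0.0612, in a range from 0.00143 to 0.107). Microglia markers were lower as a list, with none of 9 passing, 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0332, adjusted p = 0.607 with an estimated correlation). The call ended in 9 of 38 alternatives (adjusted p from 4.88e-05 to 0.607), among them those without replicate 1 of BD, Cdh3, W3 or W7 or J replicate 2 (adjusted p = 0.0568 to 0.277). Astrocyte markers rose for 1 of 3 and 2 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0361, adjusted p = 0.161 with an estimated correlation). Its call ended without BD replicate 2, W7 replicate 1 or J amacrine replicate 1 (adjusted p = 0.0881, 0.0826 and 0.0501, in a range from 0.0111 to 0.161). The count was 65 without W7 replicate 2, where Nefh, Cntnap4 and Tfap2b lost their calls (adjusted p = 0.0551 to 0.185), and Glra1 lost its call without W7 replicate 1 (adjusted p = 0.0642, the highest of a range from 0.000129 over its alternatives). With the median over the probe sets Esrrg turned to -0.19 (adjusted p = 0.763, the highest of a range from 3.86e-05), and the next probe sets of Esrrg, Nxph1 and Glra1 moved by 0.39, 0.74 and 0.35.

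ON and MP bipolar cells were compared with each other (2 against 2 arrays), 361 genes being higher in ON and 341 in MP bipolar cells. Pcp2 was 5.70 ± 0.23 higher in ON bipolar cells (52.1-fold, adjusted p = 4.86e-11), with Cnmd at 5.80 ± 1.09, Ndnf at 5.46 ± 0.39, Ablim1, the G-protein subunit gene Gng13 (5.29 ± 0.40), Hs3st4, Tpbg and Dab1. Thy1 was 6.63 ± 0.33 log2 units higher in MP bipolar cells (99.2-fold, adjusted p = 2.74e-10), which also had higher Hs3st2 (6.05 ± 0.26), Postn (5.16 ± 0.64) and the zinc finger gene Fezf2 (5.14 ± 0.23). Of 11 ON bipolar markers, 8 were higher in ON cells, among them Gpr179 (4.50), Prkca (3.59), Isl1 (3.27) and Trpm1 (1.87), and 3 did not pass (8 adjusted over the list alone, camera adjusted p = 9.91e-19). The OFF bipolar list was lower in ON cells through Fezf2 and Tacr3 (-4.88), and 8 of 10 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.0829 with an estimated correlation). Of 15 GABA and glycine receptor genes, 6 were lower in ON cells, led by Gabrb1 (-4.10) and Glra1 (-3.95), and 9 did not pass (7 adjusted over the list alone, camera adjusted p = 1.41e-05). Immunoglobulin superfamily genes were lower for 5 of 26, such as Igsf3 (-4.82), higher for Sdk2 (3.60) and Cntn4 (2.57) and did not pass for 19 (9 adjusted over the list alone, camera adjusted p = 0.00665, adjusted p = 0.107 with an estimated correlation). That call ended without ON bipolar replicate 1 (adjusted p = 0.0525, in a range from 0.00207 to 0.107). Stress and immediate early genes were lower in ON cells for 2 of 12, with Jun at -2.26, and 10 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.322 with an estimated correlation). That call ended without MP bipolar replicate 1 (adjusted p = 0.145, in a range from 0.000969 to 0.322), and Jun lost its call there and without ON bipolar replicate 2 (adjusted p = 0.0844 and 0.0641, in a range from 0.000687 to 0.0844). Ganglion cell markers were lower in ON cells for 2 of 18 and 16 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0261, adjusted p = 0.322 with an estimated correlation). The call ended in 5 of 38 alternatives (adjusted p from 0.00347 to 0.322), among them those without MP or ON bipolar replicate 1 (adjusted p = 0.0825 and 0.2). The next probe set of Gng13 moved by -0.05.

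**Figure D4:**
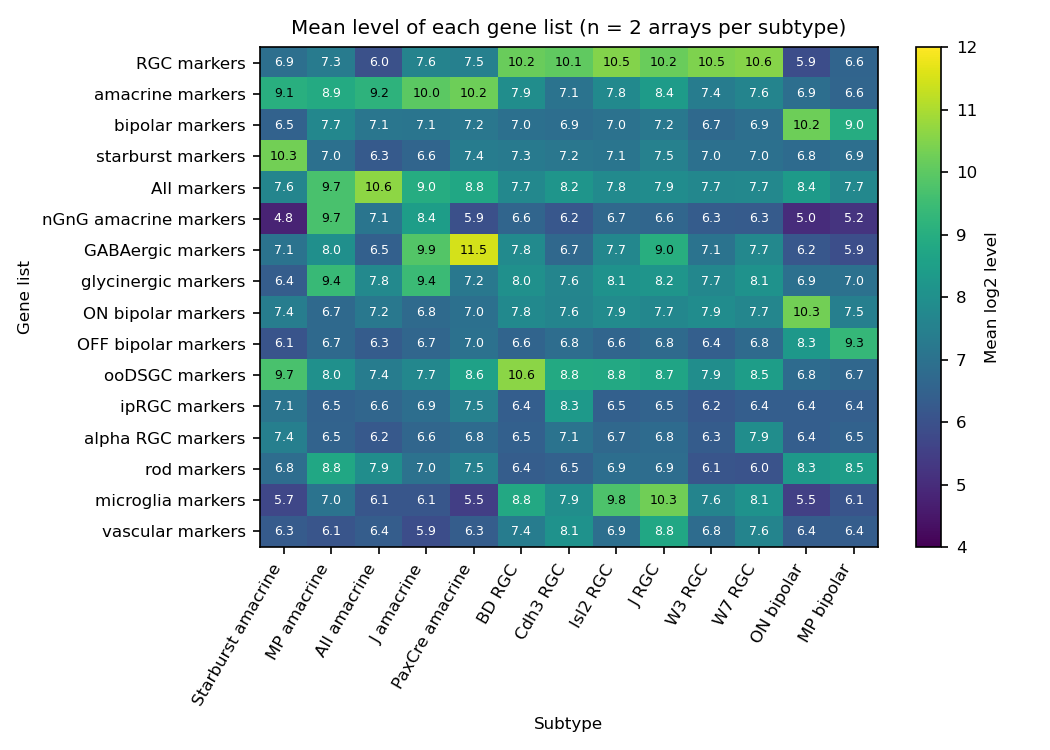
Mean level of 16 gene lists in the 13 subtypes, as log2(intensity + 16) averaged over the members of a list and 2 arrays. Starburst, AII, ON bipolar and ganglion cell markers are brightest in the subtypes or class of the same name, and microglia markers are brightest in the ganglion cell subtypes.

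In all, 432 genes were restricted to 1 subtype, passing against each of the other 12 separately. Starburst cells had 132 such genes, led by Tgfb3, at least 5.24 log2 units above any other subtype. AII cells had 79, led by Hao2 (5.58) and S100a9 (4.58) and including S100a8 (3.79), Stfa2l1 (3.71), Olfm4 (2.06) and Clec4d (1.22), ON bipolar cells 61, led by Pcp2 (5.70), and MP bipolar cells 42, led by Fezf2 (3.94). PaxCre cells had 37, with Efemp1 at 3.64, MP amacrine cells 25, with Nfix at 4.23, and J amacrine cells 20, with Loxl1 at 2.96. Ganglion cell subtypes had fewer: 19 for Cdh3, led by Gpr6 (3.37), 7 for W7, led by Hapln1 (1.86), 3 for Isl2, Pf4 (2.68), F13a1 (2.16) and Runx1 (1.16), and 3 for J, Jam2 (1.92), Stard8 (1.27) and Trpc6 (1.16). Macrophage genes, picked later, averaged 7.52 and 7.51 on Isl2, 7.18 and 7.66 on J and 6.46 to 7.19 on other ganglion cell arrays. A macrophage source of the Isl2 genes stays open. BD had Niban1 (2.19) and Lgals7 (1.45), and W3 had Cdkl4 (1.55) and Ptpn22. Genes of this paragraph outside the ranked lists were chosen after their values were seen. Within its own set of arrays, a comparison added afterwards, 792 genes were restricted.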

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

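Of the tests in this part, the class-side share of the marker lists, the same-sign share of the next probe sets, the gaps by fold, the margin of 2 SE, the weightings in the count over choices of 2 subtypes for bipolar cells, the tests of mural and other non-neuronal cells and those of ganglion cells in the amacrine and bipolar sorts were chosen only after the result was seen.

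Many genes differed between ganglion cell and amacrine arrays, and the arrays of these classes also belong to different scale sets. If separate processing made the difference, next probe sets of called genes would follow less often than in bipolar against amacrine cells: the share moving the same way by at least 1 log2 unit was 37.2% against 44.2%, a gap of 6.99 points (SE 2.28), 1.32 SE under the limit of 10 points set beforehand. That limit took no account of fold and is not relied on, since it is under 2 SE away and the gap was 2.76 points at folds of 1 to 2 log2 units, 18.6 at 2 to 3, 22.6 at 3 to 4 and 10.5 above 4. The share with the same sign was 72.9% against 87.0%, a gap of 14.2 points, so separate processing and a class difference cannot be told apart, since set and class coincide. Of the called markers, 15 of 15 for ganglion cells and 9 of 12 for amacrine cells lay on their own class's side (88.9%), which is consistent with a class difference in those genes.

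Among 100 splits of the subtypes, only the real one reached 3456 genes for ganglion against amacrine cells (highest other 2809). For bipolar cells, only the real 1 of 78 choices of 2 subtypes reached 2404 genes (highest other 2313). With equal weight for the other subtypes these were 2588 and 2540. In 100 draws that also shuffled the other classes, 3 reached 2404. They were the real one, the highest (2654, again the bipolar pair) and 1 that set MP amacrine and AII cells apart. The splits argue against chance for ganglion cells and leave it open for bipolar cells. For GABAergic against glycinergic cells 3 splits are too few (real 1256, highest other 1180).

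Mural (vessel wall) genes averaged 8.41 and 8.82 in J ganglion cells, 8.53 in Cdh3 replicate 1 and 6.21 to 7.80 on other ganglion cell arrays. Of 11 measured, 5 passed in J cells, Tbx18 (2.48), Vtn (2.42), Cspg4 (2.17), Acta2 (2.03) and Notch3 (1.44). Pdgfrb (3.55) and Rgs5 (2.61) did not pass and prompted this test. Without them the median of 9 was 1.44 (2.03 with them), 4 lying between -0.29 and 0.18. This may reflect mural cells in the sort. The mean of the 9 was 1.04 (SE 0.24) above that of 9 endothelial genes, which lay between -0.27 and 0.41 from levels (5.73 to 7.43) like those of the passing mural genes (5.07 to 7.19), and this argues against a rise of all non-neuronal cells alike. The medians were 1.70 for microglial, 0.12 for endothelial, 0.02 for macrophage and -0.23 for neutrophil genes, so a rise of some types stays open.

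Thy1 was high in sorts made without or against it. Its share of the ganglion cell level was 35.5% in starburst, 46.8% in MP amacrine and 115% in MP bipolar cells, against at most 5.14% for Nefl, Pou4f1, Slc17a6, Sncg and Rbpms. The lowest ratio of the Thy1 share to the highest of these was 9.11, which argues against ganglion cells in these sorts. In J amacrine cells Thy1 was at 15.3% and Nefl at 13.1%, but Pou4f1 was at 2.49%, Slc17a6 at 0.962%, Rbpms at 0.907% and Sncg at 0.356%, the Thy1 share being 6.15 times the second highest, which argues against ganglion cells as the whole source of Thy1 there. Transcripts of a transgene with Thy1 sequence could not be tested, since only 1 probe set of Thy1 was named.

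Lines stood out next, but each held other subtypes, so line and subtype cannot be told apart. The ganglion cell minus amacrine difference was not the same in the J line and others for 998 genes (509 higher, 489 lower). Examples were Apcdd1 (5.59) and Jag1 (5.25). For 1204 genes, the bipolar minus amacrine difference differed likewise for the MP line (660 higher, 544 lower), as for St18 (-7.17) and Rbfox1 (6.79). A dap spike control reached an intensity of 1388 on J amacrine replicate 2 and 608 on replicate 1, a signal outside the genes analysed. Among 5363 probe sets without a symbol, which no comparison names, 464 passed for starburst cells.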

How the results depend on the processing

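The added settings named in the methods were chosen only after the data were seen. Of counts under other settings, 189 of 213 stayed within 1.5 times, and of counts with an array left out, 429 of 442 did. For lists, 1550 of 1750 values kept their side and direction under other settings and 3634 of 3794 with an array left out, and 33 of 145 calls remained with an estimated correlation. For the values that moved, the cause was not tested unless the setting tests fewer genes or arrays.

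Counts that moved were, for ganglion cells against amacrine cells, 2252 with a stricter filter, which tests fewer genes, and 2128 with a pseudocount of 64; for bipolar cells 1364 with a pseudocount of 64, 1168 in the MP line alone and 1446 against amacrine cells only; and 786 (GABAergic), 959 (MP amacrine), 597 (PaxCre) and 73 (W3) with a pseudocount of 64. J amacrine cells gave 563 with the median over probe sets, 523 with array weights and 489 with a pseudocount of 64. BD gave 17 with array weights and 45 with a pseudocount of 1. Isl2 gave 19 with the stricter filter, 147 with array weights, 15 with a pseudocount of 1 and 10 with only the compared arrays. With only the compared arrays J ganglion cells gave 78, W3 68 and ON against MP bipolar cells 464, and W3 gave 208 with array weights. Restricted genes numbered 792 within a set of arrays.

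With an array left out, counts ran from 596 to 988 for PaxCre cells, from 10 to 822 for BD, 175 to 359 for Cdh3, 8 to 61 for Isl2, 40 to 387 for J, 41 to 188 for W3 and 65 to 248 for W7 ganglion cells, and all other counts stayed within 1.5 times.

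Of values of named genes, 4944 of 5071 kept their side and direction under other settings and 10284 of 10412 with an array left out. Values that reversed with the median over probe sets were Zfp248 in J ganglion cells (-1.82 to 0.19) and Esrrg in W7 ganglion cells (2.72 to -0.19), Cdh13 in starburst cells (-2.90 to 0.014), Pcdh18 (1.03 to -0.67) and Top2a (2.36 to -0.09) in PaxCre cells, Gad2 in J amacrine cells (-0.63 to 0.19) and Slc6a9 in MP amacrine cells (-0.07 to 0.024). In bipolar cells Prox1 was at -3.31, Neurod1 at -0.17 and Sag at -0.11 in the MP line alone, and Prox1 was at -0.65 against amacrine cells only. Slc6a9 in MP amacrine cells was at 0.017 with a pseudocount of 1, 0.22 without replicate 2 and -0.35 without replicate 1. Slc5a7 in starburst cells was at -0.24 without replicate 2 and 0.76 without replicate 1. For the list of microglia markers in Cdh3 RGC vs other RGC, the signed log10 camera p was 1.85 without Cdh3 replicate 2, on the higher side, and -14.07 without replicate 1. The cause was not tested.

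Replicate numbers do not pair arrays: 21 of 78 subtype pairs correlated above 0.1, from -0.23 to 0.37. With the replicate number as a block, 3456 genes passed for ganglion cells against amacrine cells and 1264 for GABAergic cells, and no count moved by over 1.5 times. Of 216 named values, 105 had a next probe set, and 73 of these moved the same way by at least 1. Differences near the floor (log2 4.09) are understated.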

Other observations

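The test of the genes on either side of Cdh3 was chosen only after the result was seen.

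Genes of GABAergic amacrine cells also differed outside the amacrine class. All 6 markers were lower in bipolar cells, with Tfap2c at -3.12 and Gad1 at -2.90 (6 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.184 with an estimated correlation). Among ganglion cells, 3 of 6 rose in J cells, Tfap2c (3.72), Gad1 (2.61) and Lhx9 (1.29), and 3 did not pass (4 adjusted over the list alone, camera adjusted p = 4.09e-06, adjusted p = 0.0533 with an estimated correlation). In W3 cells Gad1 fell (-1.86) and 5 of 6 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.285 with an estimated correlation).

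Markers of amacrine cells with neither GABA nor glycine were lower on the GABAergic side for 4 of 5, led by Ppp1r17 (-4.91) and Neurod2 (-3.95), and Gbx2 rose (1.48; 5 adjusted over the list alone, camera adjusted p = 0.00042, adjusted p = 0.0625 with an estimated correlation). They rose in J amacrine cells for 3 of 5, Ebf3 (3.87), Ppp1r17 (2.62) and Neurod6 (2.03), and 2 did not pass (3 adjusted over the list alone, camera adjusted p = 0.00252, adjusted p = 0.104 with an estimated correlation). Of 13 classical cadherins, 5 rose in PaxCre cells, such as Cdh4 (2.80) and Cdh10 (2.76), Cdh1 fell (-3.39) and 7 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00655, adjusted p = 0.0796 with an estimated correlation).

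Cdh1 was high in Cdh3 ganglion cells (4.26 ± 0.29) and in AII cells (5.13 ± 0.29), and Zfp90, the other immediate neighbour of Cdh3 among the tested genes, rose in Cdh3 ganglion cells (2.93 ± 0.20, limma adjusted p = 4.59e-08) but was at 0.09 in AII cells. The nearest 4 tested genes on either side without Cdh1 had a median of 0.13, which argues against a broad effect of the reporter construct. That median cannot test an effect limited to the immediate neighbours. Both were higher, 1 of only 9 such adjacent pairs among 13894. So Cdh1 and Zfp90 may reflect the construct, which was not shown.

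AII and Cdh3 mice share a Swiss Webster background. AII and Cdh3 cells shared 72 calls in the same direction, against 22.1 expected, and 63 in opposite directions. The ratio of 3.26 for the same direction ranked 13 of 30 combinations of amacrine and ganglion cell subtypes, which leaves a strain effect undecided.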
